A study of Drosophila melanogaster with 3 samples.

How the data were processed

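Binding sites of E(bx) carrying C-terminal green fluorescent protein were measured by chromatin immunoprecipitation with sequencing in 3 biological replicates of whole fruit fly embryos (0 to 16 h, both sexes pooled). Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp. The labels' description says that the antibody was against the fluorescent protein, while their antibody field reads E(bx). The description was followed, and whether untagged E(bx) was precipitated too is not settled by the labels. All 3 libraries belong to 1 group, taken from the labels together with the replicate numbers, and each has a biosample of its own.

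The deposited files used were lists of peaks. For each build (dm6 and dm3) there was a list per replicate, a list called on the reads of all replicates pooled, and an optimal IDR set. Per the deposited file records, peaks were called from the libraries' alignments with a control, and the dm6 IDR set derives from the pooled list and the 3 replicate lists. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here, and control data were not analysed here. The replicate lists are relaxed lists meant as input to IDR and include background. In dm6 they held 30000, 28972 and 30000 peaks for replicates 1, 2 and 3, and the pooled list 30000; 1 peak of the pooled list and 1 of replicate 1 lay on Y and were left out.

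Column 7 of the deposited lists holds the peak's signal value as the authors' caller wrote it. Its scale is not stated, so it was used mainly to rank or describe peaks within a list. Ratios of its medians, its correlations between libraries and the rescaling on X treat it as a quantity and rest on that unstated scale. Column 9 of the deposited lists holds the −log10 q-value; it was 4.39 for every peak of the dm6 IDR set and could not rank them. The p-value column holds -1 throughout and was not used. The summit is the deposited start plus the deposited offset. The files give no read counts, so the depth per library is unknown and no interval that needs it was computed.

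Peak coordinates are dm6 and were set against the Release 6 genome sequence, which has the same arms and reaches past every peak, and against the gene models of Ensembl release 115. Transposable elements of that annotation were not counted as genes. This left 18164 genes on the 6 arms, 13945 of them protein-coding, with 23581 distinct start sites, or 21788 clusters after merging those within 100 bp. Positions are given counting from 1. The dm3 lists were used only for counts and were neither annotated nor converted.

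A promoter peak is a peak with its summit within 500 bp of any annotated TSS. Each summit was assigned to 1 class, in the order TSS window, coding sequence, 5′ UTR, 3′ UTR, non-coding exon, intron and intergenic. Chance levels came from 1000 seeded random placements of the same number of summits on the same arm, leaving out unknown bases. Replicates were compared through the best 9708 peaks of each replicate list, matched within 200 bp, with 100 seeded circular shifts per arm as the chance level. Medians of log2 signal were compared with a permutation test of 100000 resamples. Peak density on X and chromosome 4 was set against 2L, 2R, 3L and 3R per TSS cluster with an exact binomial test.

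The 26 gene lists and 17 consensus sequences were fixed before the data were examined, as were all tests and alternatives unless stated otherwise. List symbols were matched to the annotation, 6 of them through synonyms in RefSeq's gene table (for example Dl as Delta and h as hry), with 0 unmatched. A list's share of genes with a promoter peak was compared with all other protein-coding genes, or with all other genes for lists holding non-coding genes, by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. As an alternative, 10000 random lists matched on the number of TSS clusters were drawn. Motifs were searched on both strands in 201 bp windows centred on the summit and in windows 1000 bp to one side, the side drawn at random. No pairing applies to a single group.

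The genes named are those next to the 10 strongest peaks, all members of the Hox, NURF and ISWI and dosage compensation lists, and of every other list the 2 members with the strongest promoter peak and the first 2 in alphabetical order without one. The gene with the most summits in its body was named as well.

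Alternatives tried were start site windows of 250 and 1000 bp, matching within 100 or 500 bp or by overlap of the regions, other list lengths, the 4854 strongest peaks in place of all, and each library's own best peaks. Protein-coding start sites alone, density per sequence length, motif windows of 50 and 200 bp to each side, a shuffle that keeps dinucleotides, and start sites without a peak as motif control were also tried. Leaving out a replicate meant keeping the IDR peaks matched in both other libraries, since the IDR set itself could not be remade. It gave 7811, 7824 and 8453 peaks without replicates 1, 2 and 3. The libraries' own lists set against each other, all pooled peaks outside the IDR set as a comparison for its promoter share, start site windows for genes with and without a peak, a single summit per region, transposable elements counted as genes, and an X signal rescaled by 0.75 or by the ratio observed at housekeeping genes were added after the data were seen.

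The functions were tested on simulated peak sets of 9708 summits. A promoter share of 60% was recovered as 60.0%, a signal ratio of 2 as 1.97, and lists planted at 90% and 5% as 90.4% and 4.47%, with both called and 0 of the 24 other lists called. In random windows 0 of 17 motifs were called. A share found in all 3 libraries of 50.4% came out as 54.3%. A dropped peak still counted as found where a neighbouring summit lay within 200 bp, and 344 gaps between summits of the set were that short. How much of the excess this gives was not tested. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.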

Results

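E(bx), also known as NURF301, is the largest subunit of NURF, a nucleosome remodelling complex whose motor is the ATPase Iswi. Its binding sites were mapped by chromatin immunoprecipitation with sequencing in whole fruit fly embryos of mixed sex collected from 0 to 16 h, from a transgenic line that carries E(bx) with green fluorescent protein at its C terminus, with an antibody that the description gives as raised against the fluorescent protein and the antibody field as E(bx). There was 1 group of 3 biological replicates, each from its own biosample, and nothing was compared between groups. The questions answered here were where in the genome the tagged protein was found, at which genes and next to which sequences. The peak lists give no read totals, so the depth of the libraries is unknown, and intervals given for shares cover counting error only. Peaks were called with a control, but control data were not analysed here. Loci that precipitate with any antibody therefore cannot be set apart in these results, including the peaks at promoters and at housekeeping genes.

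The authors' reproducible peak set (optimal set of the irreproducible discovery rate procedure, IDR) on the dm6 build held 9708 peaks, all on the arms 2L, 2R, 3L, 3R, 4 and X. They had a median width of 441 bp (range 116 to 2061 bp) and covered 3.59 Mb, or 2.68% of the 133.6 Mb of sequence on these arms. The 9708 peaks lay in 8748 separate regions, of which 927 carried more than 1 summit. Every peak of the set was also part of the list called from the pooled reads, and the set was exactly the 9708 peaks of that list with the highest signal value. The signal value is the authors' own score per peak, on a scale that is not stated, so ratios of it are descriptive. It ran from 156 to 11961 with a median of 519.

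The libraries' own lists overlapped. Of the 9708 best peaks of replicate 1, 76.6% had a summit within 200 bp among the best 9708 of both other replicates, against 76.7% for replicate 2 and 80.1% for replicate 3. Circular shifts gave 0.0719 to 0.0749% (permutation p = 0.0099 each, the smallest that 100 shifts can give). By pairs the share was 90.6 to 90.8% between replicates 1 and 2 and 80 to 84.6% between replicate 3 and either of them. A neighbouring peak's summit within 200 bp counts as a match too, here and below, which can raise such shares. The reproducible set holds the strongest peaks of these same libraries' pooled reads, so its recovery in each is not independent evidence and is given as a description. Among each library's own 9708 best peaks, a summit within 200 bp was present for 91.4% of the reproducible peaks in replicate 1, 91.5% in replicate 2 and 87.8% in replicate 3 (mean 90.2% ± 2.09, SD, n = 3). All 3 libraries had such a summit at 7481 peaks (77.1%, 95% Wilson interval 76.2 to 77.9), exactly 2 libraries at 1645, 1 library at 545 and none at 37. After circular shifts of the libraries' peaks along each arm, which do not imitate that dependence, the share found in all 3 averaged 0.00288%. With only the 4854 best peaks of each library the share was 41.8%, which such short lists hold down by construction. Across matched peaks, which are not independent replicates, Spearman's rho of the signal value was 0.938 between replicates 1 and 2 (Pearson's r of log2 signal 0.911), 0.809 between replicates 1 and 3 (r = 0.748) and 0.807 between replicates 2 and 3 (r = 0.753).

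Peaks of tagged E(bx) lay mainly at promoters. Of the 9708 summits, 7196 (74.1%, 95% Wilson interval 73.2 to 75.0) were within 500 bp of an annotated transcription start site (TSS), against 13.6% for random positions on the same arms, a 5.46-fold difference. Coding sequence outside these windows held 0.608% of summits against 14% at random, introns 13.2% against 39.5%, intergenic sequence 9.19% against 27.1% and 3′ UTRs 1.77% against 4.46%. The permutation p was 0.002 for each of these classes, the smallest that 1000 placements can give, while 5′ UTRs outside the windows held 0.752% against 0.607% (p = 0.0879). Weaker peaks of the pooled list, over 1000 bp from any reproducible summit, lay at a TSS in 3247 of 16590 cases (19.6%), 54.6 points below the reproducible set (Fisher's exact test, two-sided, log10 p = -1702). Keeping that distance takes the occupied promoters out of the space left to them and so lowers their share by construction. In that space random positions lay at a TSS in 9.01% of cases, so the weaker peaks were 2.17 times as often there (permutation p = 0.002, the smallest that 1000 placements can give), against 5.46 times for the reproducible set. Without the distance rule 5200 of all 20291 pooled peaks outside the set (25.6%) lay at a TSS, 48.5 points below it, a comparison added after the data were seen.

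Promoter peaks were also the stronger ones. Their median signal value was 614 (interquartile range 323 to 1017, n = 7196), against 311 (208 to 571, n = 2512) for the distal peaks over 500 bp from any TSS, a ratio of 1.98 (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest it can give). The promoter share was 85.4% among the 4854 strongest peaks and 62.9% among the other 4854 (Fisher's exact test, p = 3.79e-144). Within the 4854 strongest peaks the signal ratio was 1.13 (permutation p = 1e-05), as this selection removes weak peaks of both classes.

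**Figure D1:**
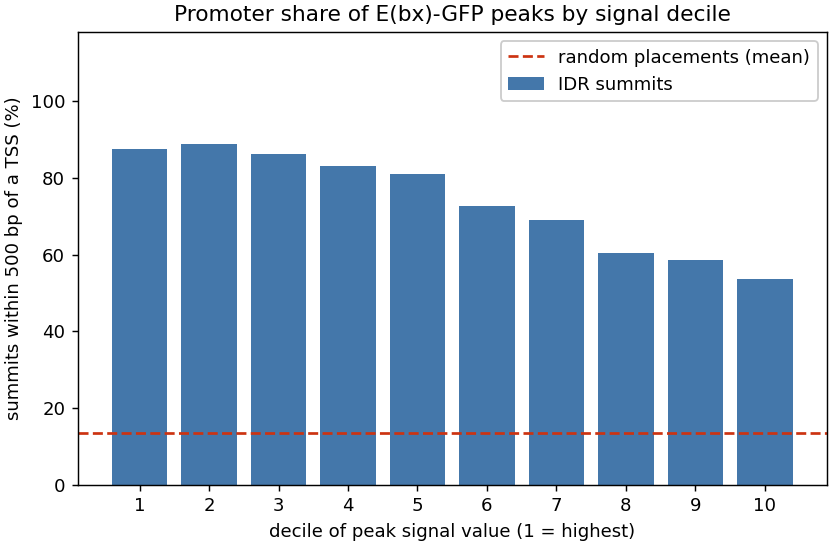
Percentage of reproducible summits within 500 bp of a TSS (y axis) in each decile of the peaks' signal value (x axis, 1 is the highest), with the mean of random placements as a dashed line. The share is 87.5% in decile 1, 88.8% in decile 2 and 53.6% in decile 10, and random placements give 13.6%.

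Summits sat just upstream of start sites. Over the 7196 promoter peaks the median position was 44 bp upstream of the nearest TSS (-44 bp, interquartile range -102 to -9), with 5770 summits upstream and 1395 downstream (80.5% upstream; two-sided exact binomial test, log10 p = -624). At protein-coding genes with a single TSS and no other gene's TSS within 2000 bp, the median was -48 bp, and 963 summits lay upstream against 171 downstream (84.9% upstream, exact binomial p = 2.48e-134). Divergent genes, whose TSS lies within 1000 bp of that of a protein-coding gene on the other strand, carried a promoter peak in 4094 of 5052 cases (81.0%), and other protein-coding genes in 2924 of 8893 cases (32.9%; Fisher's exact test, two-sided, log10 p = -687). A peak between divergent genes counts for both partners, so these genes are not independent of each other. A peak at the partner's start site can also lie within 500 bp of the gene's own. This raises the share of divergent genes by construction, by an amount not estimated here.

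**Figure D2:**
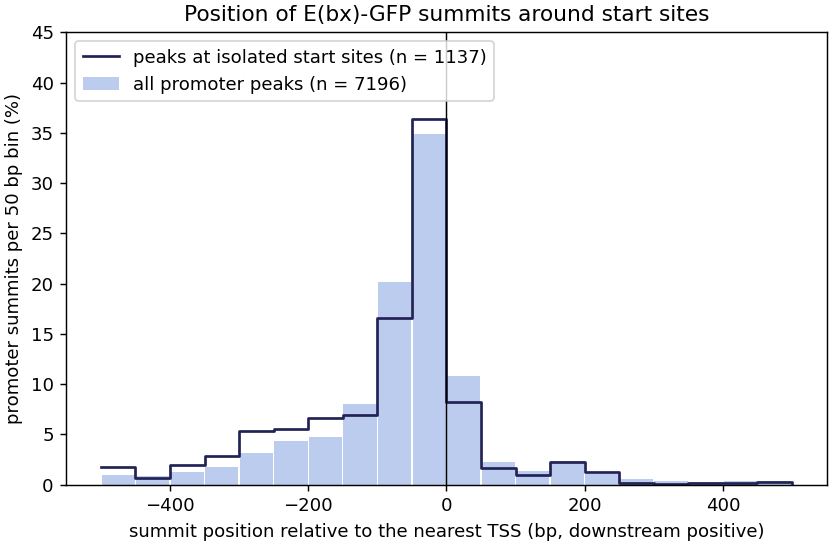
Percentage of promoter summits in 50 bp bins (y axis) by their position relative to the nearest TSS in the direction of transcription (x axis, bp). Filled bars show all 7196 promoter peaks and the line shows the 1137 at isolated protein-coding start sites; both are highest in the bin from -50 to 0 bp.

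The strongest peak of the genome lay at the gene of the tagged protein itself. It spanned 246214 to 247403 on 3L (dm6) with its summit at 246984, 72 bp upstream of the start site of E(bx) (FBgn0000541, 3L 233926 to 246912, minus strand). Its signal value was 11961 in the pooled list, against 5286 for the next peak, and it ranked first in each replicate's own list (signal values 4056, 4990 and 3007 in replicates 1, 2 and 3). The line is transgenic for this gene, and the number of copies of the locus in the precipitated DNA was not analysed here. Whether the control used in calling peaks came from the same line, and so carried the same copies, is not given in the sources used here.

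Of the other peaks among the 10 strongest, 6 were at start sites. The nearest genes were sowah (signal 4937, 32 bp upstream), CG17883 (3672), nudC (3616, a gene of the dynein and nuclear migration pathway), mRpL13 (3524, a mitochondrial ribosomal protein), the transfer RNA gene tRNA:Pro-CGG-2-3 (3511) and zpg (3452, a germline gap junction protein). Start sites of further genes lay within 500 bp of some of these summits, of CG10602 at the mRpL13 peak, of CG13380 and CG4174 at the tRNA:Pro-CGG-2-3 peak and of Rexo5 at the zpg peak. The 3 others were intergenic, 1705 bp upstream of CG5568 (signal 5286), 995 bp upstream of RabGGTa (3628) and 550 bp upstream of CheB93b (3447). The peak at CG17883 ranked 4 and 5 in the lists of replicates 1 and 2 but 1425 in that of replicate 3. The gene with the most summits inside its body was Eip75B, an ecdysone-induced nuclear receptor gene of 114 kb on 3L (17950953 to 18064696), with 17.

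Promoter peaks were present at 7018 of 13945 protein-coding genes (50.3%), 405 of 3261 non-coding RNA genes (12.4%) and 29 of 268 pseudogenes (10.8%). Of 26 gene lists fixed before the data were examined, 10 had a higher share of genes with a promoter peak than the other genes and 9 a lower share (Fisher's exact test, two-sided, Benjamini-Hochberg over the 26 lists). Random lists matched on the number of start sites gave the same counts, 10 and 9. Among the 4854 strongest peaks 6 lists were higher and 11 lower.

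Ribosomal protein, proteasome and cell cycle genes mostly had a promoter peak. A promoter peak was found at all 73 mitochondrial ribosomal protein genes (Fisher's adjusted p = 1.27e-21), 83 of 88 cytosolic ribosomal protein genes (94.3%, adjusted p = 1.06e-18), 31 of 32 proteasome genes (96.9%, adjusted p = 4.38e-08) and 33 of 34 cell cycle and replication genes (97.1%, adjusted p = 1.31e-08), against about 50% of other protein-coding genes. The strongest were mRpL13 (signal 3524) and mRpL53 (2752), RpL34b (2863) and RpL7 (2447), Prosbeta1 (2613) and Prosbeta5 (2181), and fzy (1990) and Dp (1989), which encode an activator of the anaphase-promoting complex and the partner of E2F. Without a promoter peak were RpL10Aa and RpL32 among the cytosolic ribosomal genes, Prosalpha1 in the proteasome and stg, the Cdc25 phosphatase that drives entry into mitosis.

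The Polycomb and trithorax, NURF and ISWI, and dosage compensation lists had a promoter peak at every member. All 25 Polycomb and trithorax genes carried one (95% Wilson interval 86.7 to 100%, Fisher's adjusted p = 1.54e-07), led by Pc (signal 2580, rank 55) and trx (2379, rank 82). So did all 8 NURF and ISWI complex genes (67.6 to 100%, Fisher's adjusted p = 0.0119): besides E(bx), Iswi had a signal of 1166, Caf1-55 of 1027, Chrac-14 of 1014, Acf of 977, tou of 488, Nurf-38 of 417 and Chrac-16 of 339. The peak named at Chrac-16 had its summit over 250 bp upstream of the gene and would not count for it with the 250 bp window. The NURF and ISWI list counts E(bx), the gene of the tagged protein, whose number of copies was not analysed here. Its test was not repeated without that gene. Among the 4854 strongest peaks the call for this list ended (24.7 points above other genes, Fisher's adjusted p = 0.203). All 7 dosage compensation genes had a promoter peak too, compared with 42.3% of all other annotated genes (Fisher's adjusted p = 0.00392): msl-2 (1558), msl-1 (1193), msl-3 (883), the roX2 RNA (674), the helicase gene mle (655), the roX1 RNA (642) and mof (332).

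Developmental control genes were divided. Segmentation genes had a promoter peak in 22 of 27 cases (81.5%, Fisher's adjusted p = 0.00261), with bcd, the anterior morphogen, at 2682 and oc at 1530, while ftz and gt had none. Wnt pathway genes had one in 16 of 20 cases (80%, Fisher's adjusted p = 0.0169), with arr, the Wnt co-receptor, at 1638 and Apc at 1589, and none at Notum and Wnt10. Both calls ended when any 1 of the 3 replicates was left out, that is among the peaks matched in both other libraries (segmentation 3.41 to 19.6 points above other genes, Wnt 16.6 to 22.9). The same was seen in the libraries' own lists of replicates 1 and 2, though not of replicate 3, where segmentation genes were 36.2 points above other genes (Fisher's adjusted p = 0.000306) and Wnt genes 31.0 (adjusted p = 0.00907). Both ended also among the 4854 strongest peaks (2.98 points with Fisher's adjusted p = 0.843 for segmentation, 17.3 points with adjusted p = 0.203 for Wnt). The peaks named at oc and Apc had summits over 250 bp upstream of the gene and would not count for it with the 250 bp window.

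Of the Hox genes, which set segment identity, lab (signal 775), Scr (592), abd-A (490), pb (322) and Abd-B (280) had a promoter peak and Antp, Dfd and Ubx did not (5 of 8, 62.5%, Fisher's adjusted p = 0.821). Antp held 6 summits and Ubx 2 elsewhere in their bodies. Further lists not past the threshold were dorsoventral and mesoderm genes (12 of 19, Fisher's adjusted p = 0.467; Mef2 1050 and pnr 712, none at bap and bin), which among the 4854 strongest peaks turned to 27.3 points below other genes (-27.3, adjusted p = 0.0256), and JAK/STAT genes (8 of 12, adjusted p = 0.48; Socs36E 2115 and dome 968, none at et and upd1). The same held for the Notch pathway and E(spl) genes (10 of 17, Fisher's adjusted p = 0.743; neur 1589 and H 1588, none at E(spl)m5-HLH and E(spl)m8-HLH). Ecdysone response genes (12 of 22, Fisher's adjusted p = 0.832) were led by Hr39 (1839) and ftz-f1 (1291), with none at br and Eip63F-1. Neuronal genes (9 of 16, Fisher's adjusted p = 0.832) were led by Syx1A (1228) and unc-13 (951), with none at brp and ChAT. Heat shock genes (8 of 17, Fisher's adjusted p = 0.832) were led by DnaJ-1 (1049) and Hsp68 (838), with none at CG4456 and Hsp67Ba. This list includes several Hsp70 copies, and how reads that match several copies were treated is not given in the sources used here.

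Several lists of genes for adult or specialised functions had few promoter peaks. Cuticle protein genes had a promoter peak in 4 of 92 cases (4.35%, Fisher's adjusted p = 1.56e-21), among them Lcp9 (1086) and Lcp2 (493) but not Ccp84Aa or Ccp84Ab. Chemosensory receptor genes had one in 8 of 179 cases (4.47%, Fisher's adjusted p = 1.44e-40), with Gr63a at 1339 and Ir60e at 718 and none at Gr10a and Gr10b. The share was 1 of 18 for egg shell and yolk genes (5.56%, Fisher's adjusted p = 0.000163; Vm32E, 750; not Cp15 or Cp16), 2 of 20 for antimicrobial response genes (10%, adjusted p = 0.000437; Rel, 502, and AttD, 416; not AttA or AttB) and 2 of 18 for testis Mst genes (11.1%, adjusted p = 0.00125; Mst85C, 1263, and Mst36Fa, 1246; not Mst27D or Mst33A). The peaks named at Lcp9, Lcp2, Gr63a, Ir60e, Vm32E and AttD had summits over 250 bp upstream of the gene. They would not count for it with the 250 bp window, and other genes' start sites near them are not listed here.

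Muscle structure genes had a promoter peak in 2 of 18 cases (11.1%, Fisher's adjusted p = 0.00125), Tm1 (2683), a tropomyosin gene, and Zasp52 (209), with none at Act57B and Act79B. Markers of glia, hemocytes and fat body had one in 2 of 13 cases (15.4%, Fisher's adjusted p = 0.0169), the glial regulator repo (293) and ush (213), with none at Col4a1 and gcm. The call for these markers ended with a TSS window of 250 bp (-30.0 points, Fisher's adjusted p = 0.0642) or 1000 bp (-23.2 points, adjusted p = 0.142).

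Genes transcribed into small RNAs went both ways. The transfer RNA list held 295 genes by biotype or name, 290 of them by biotype. Of the 295 genes, 192 (65.1%) had a summit within 500 bp, compared with 41.9% of the other annotated genes (Fisher's adjusted p = 8.92e-15). Neighbouring genes can share a peak, so this p treats dependent genes as independent, and the strongest peaks at these 192 genes were 131 different ones. Among genes with no other start site within 1000 bp, 26 of 70 transfer RNA genes (37.1%) and 26.8% of others had a peak (odds ratio 1.62, 95% interval 0.954 to 2.69). This interval includes 1, and with 70 genes a smaller difference cannot be told from none. The highest signals were at tRNA:Pro-CGG-2-3 (3511) and tRNA:Thr-AGT-1-4 (3034), with none at tRNA:Ala-AGC-1-1 and tRNA:Ala-AGC-2-10. Many transfer RNA genes have several copies, and how reads that match several copies were treated is not given in the sources used here. Among the 4854 strongest peaks the difference turned to -10.9 points (Fisher's adjusted p = 0.000111), so peaks at transfer RNA genes were common but mostly weak. Small nuclear and nucleolar RNA genes had a promoter peak in 39 of 301 cases (13%), against 42.8% of all other annotated genes (Fisher's adjusted p = 1.13e-27). Most of those others are protein-coding, and the share among non-coding RNA genes was 12.4%. By biotype the share was 28.1% for small nuclear RNA genes (9 of 32) and 11.2% for small nucleolar ones (30 of 269). Whether the annotated starts of these small RNA genes are promoters was not examined. Their strongest peaks were at snoRNA:Me18S-G1358c (2351) and snoRNA:Or-aca4 (2067), with none at scaRNA:MeU1b-A234 and scaRNA:MeU2-48.

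None of the 111 replication-dependent histone genes, such as His1:CG31617 and His1:CG33801, had a promoter peak (95% Wilson interval 0 to 3.35%, Fisher's adjusted p = 1.55e-33). These genes are near-identical copies in a repeat array on 2L (21416953 to 21541681), where the relaxed pooled list had 2 summits and the reproducible set 0. How reads that match several copies were treated is not given in the sources used here, so this absence is uncertain.

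**Figure D3:**
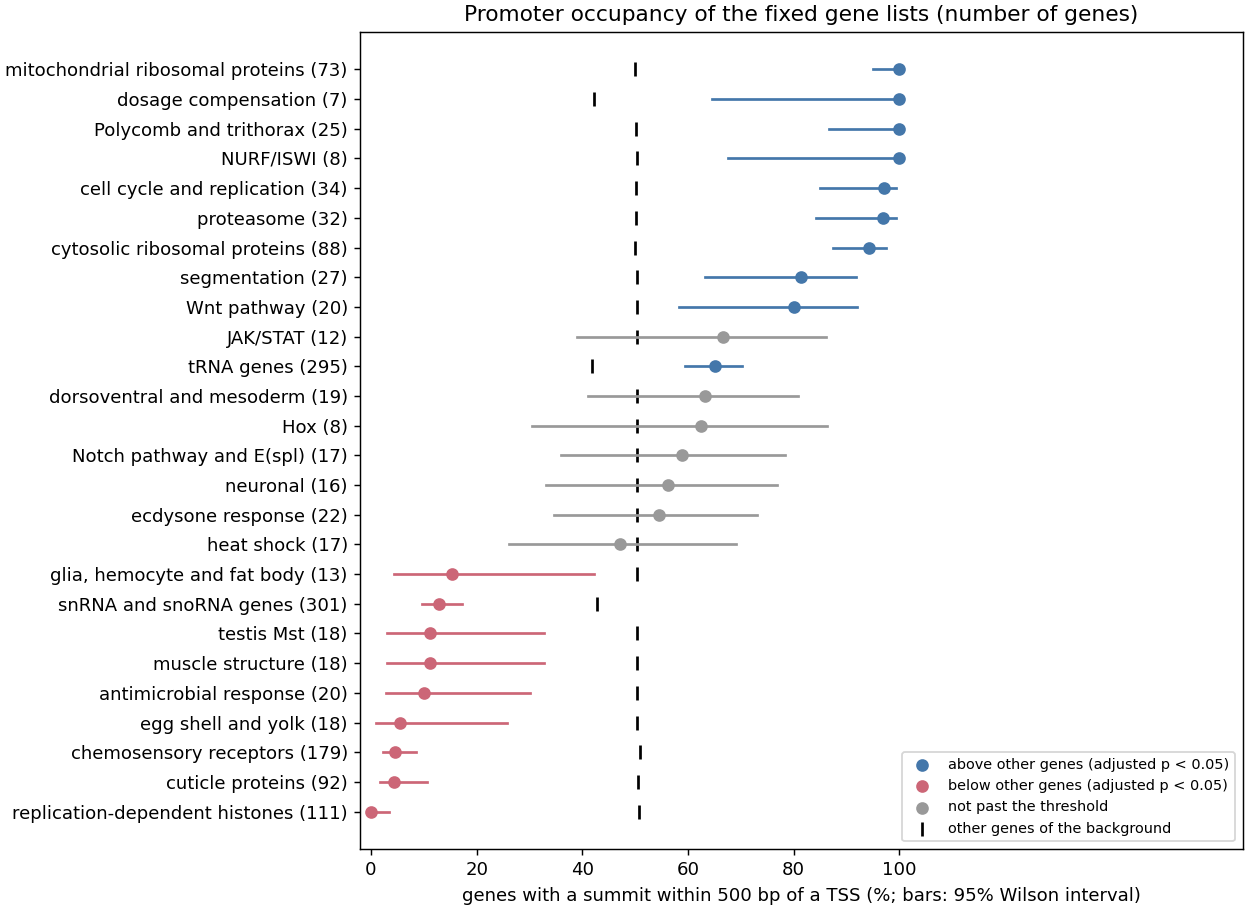
Percentage of each fixed list's genes with a summit within 500 bp of a TSS (x axis; points, with 95% Wilson intervals as bars) for the 26 lists (y axis, number of genes in brackets), with the share of the other genes of the background as black ticks. Mitochondrial ribosomal protein, dosage compensation, Polycomb and trithorax, and NURF and ISWI genes are at 100%, and replication-dependent histones at 0%.

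Sequence elements of housekeeping promoters were among those more frequent at the summits. The DRE (TATCGATA), the site of the factor Dref, was present within 100 bp of 9.52% of summits against 0.608% of windows 1000 bp to one side, 15.7 times as often (exact McNemar adjusted p = 9.9e-201). Motif 1 (GGTCACAC), bound by M1BP, was found at 8.84% against 0.505% (exact McNemar adjusted p = 9.62e-194), Motif 6 (GGTATTTT) at 5.45% against 1.15% (adjusted p = 1.22e-65) and Motif 7 (CAKCNCTR) at 18.5% against 7.19% (adjusted p = 7.4e-126). Other elements rose too: the GAGA repeat (9.85% against 3.26%), the CTCF core (6.16% against 2.31%), the Su(Hw) core (4.66% against 2.09%) and the CAGCTG E-box (16.0% against 10.3%). Most summits lay at promoters, so windows beside them do not separate traits of summits from traits of promoters. A comparison added after the data were seen took windows centred on start sites, with a peak and with none within 1000 bp. There the DRE was at 13.2% against 0.866%, the GAGA repeat at 5.59% against 3.54% and the CAGCTG E-box at 19.1% against 8.18%. The CTCF core was at 2.08% against 1.39% and the Su(Hw) core at 1.59% against 1.61%. Of 17 fixed consensus sequences, 12 were more frequent at summits than beside them, 3 less frequent and 2, the initiator and the STAT site, not past the threshold (two-sided exact McNemar test, Benjamini-Hochberg over the 17). Presence of a consensus says nothing of its occupancy by a factor.

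Promoter and distal summits carried different elements. The DRE was at 12.2% of the 7196 promoter summits and 1.71% of the 2512 distal ones, Motif 1 at 11.6% against 0.995%, and Motif 6 at 6.75% against 1.71%. The reverse held for the GAGA repeat, which the GAGA factor binds (6.75% against 18.7%), for the cores of the insulator proteins CTCF (3.65% against 13.3%) and Su(Hw) (2.52% against 10.8%), and for CA repeats (4.68% against 12.4%). All 7 differences passed Fisher's exact test, two-sided, with adjusted p from 4.63e-79 (Motif 1) to 4.71e-26 (Motif 6). The initiator, a core promoter element at the start site itself, was present within 100 bp of 22.0% of the 6495 start sites nearest to promoter peaks and of 34.8% of 11084 start sites with no peak within 1000 bp (Fisher's adjusted p = 1.32e-73), and the TATA box at 23.4% against 29.5% (adjusted p = 1.77e-18). Both kinds of window were centred on the start site, in a comparison added after the data were seen. With windows at the summits of promoter peaks, part of which miss the start site, the share with an initiator was lower still (17.8%).

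The TATA box was otherwise more frequent at summits than 1000 bp beside them (25.6% against 19.5%, exact McNemar adjusted p = 7.11e-24), but windows of 50 bp to each side gave -0.505 points (adjusted p = 0.32). The less frequent ones were the Zelda site (0.855% against 1.37%, exact McNemar adjusted p = 0.00106), the GATA site (4.58% against 5.47%, adjusted p = 0.00666) and the Twist E-box (8.6% against 9.49%, adjusted p = 0.0393). With a shuffled control that keeps dinucleotides, the deficit at the GATA site turned (0.165 points, exact McNemar adjusted p = 0.679). That at the Twist E-box turned too (0.0206 points, exact McNemar adjusted p = 0.979). The deficit at the Zelda site ended with this control (-0.0412 points, exact McNemar adjusted p = 0.869). At start sites with a peak the GATA site stayed rarer than at those without (4.26% against 7.41%, Fisher's adjusted p = 3.94e-17). So did the Zelda site (0.754% against 1.18%, Fisher's adjusted p = 0.00848). The Twist E-box was not past the threshold there (-0.777 points, Fisher's adjusted p = 0.0589). These windows were centred on start sites, in the comparison added after the data were seen.

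**Figure D4:**
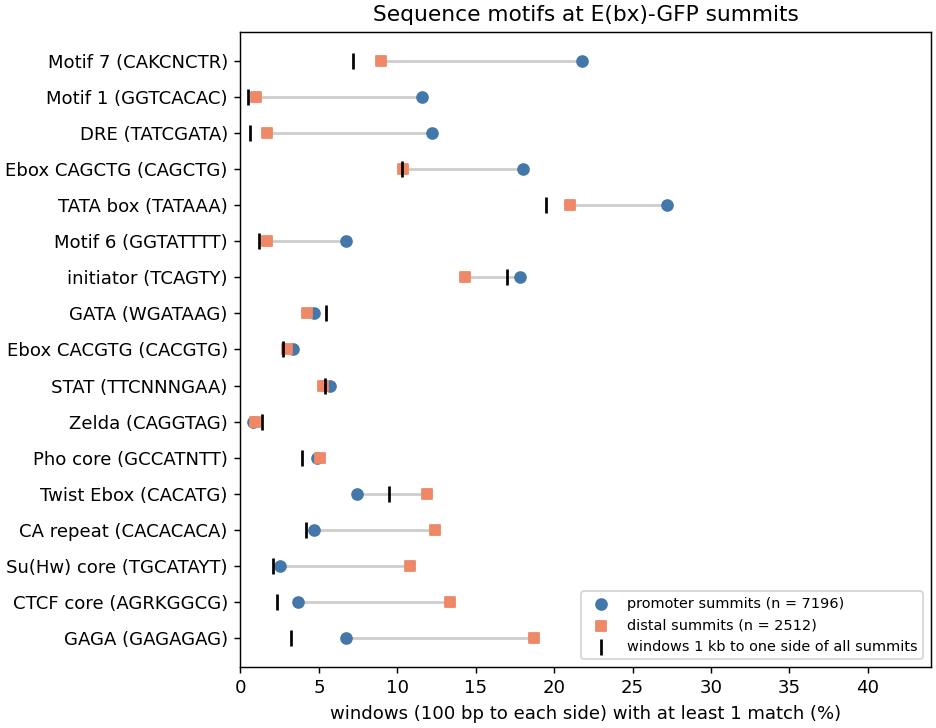
Percentage of windows reaching 100 bp to each side that hold at least 1 match on either strand (x axis) for 17 consensus sequences (y axis), at promoter summits (circles, n = 7196), at distal summits (squares, n = 2512) and in windows 1000 bp to one side of all summits (black ticks). Motif 7, Motif 1 and the DRE lie farthest to the right at promoter summits relative to distal ones, and the GAGA repeat the other way.

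Peak number differed between chromosomes. The X carried 0.504 peaks per TSS cluster (1783 peaks) against 0.431 on the large autosomal arms, a ratio of 1.17 (95% interval 1.11 to 1.23, two-sided exact binomial test, p = 5.12e-09), and 1.06 per sequence length. Among the 4854 strongest peaks the direction turned, to a ratio of 0.896 (0.827 to 0.971, exact p = 0.00664). The median signal value was 412 on X and 535 to 576 on 2L, 2R, 3L and 3R. The small chromosome 4, which is rich in heterochromatin, had 129 peaks, or 0.746 per TSS cluster. Its ratio to the large autosomal arms was 1.73 (1.44 to 2.06, exact p = 1.47e-08), and 1.35 per sequence length (1.13 to 1.61, exact p = 0.00117). Its promoter share was 69.0%, that of X 69.3% and those of the large autosomal arms 72.7 to 78.2%.

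On the older dm3 build the reproducible set held 9423 peaks, 97.1% of the number on dm6. Coordinates were not converted between the builds, so it is not known how many peaks are shared. The dm3 set's record names the pooled list and 1 replicate's list as its sources, and the dm6 set's record names the lists of all 3 replicates.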

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

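Chosen only after results were seen were the library ratios at E(bx), the density of weak peaks on X, the withdrawal of the verdict on extra copies that rests on it, and the tests of transfer RNA genes that stand alone and of groups of neighbours; the other tests here had their outcomes written down first.

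In the dm3 reproducible set, used here only for its number of peaks, 67 of 9423 peaks (0.711%) lay on heterochromatic or unplaced sequences: 22 on 3LHet, 21 on 2RHet, 13 on 3RHet, 5 on XHet, 3 on 2LHet and 3 on U. The highest signal among them was 3162, on 3LHet. They were singled out as signal in data not otherwise used, and no control level was analysed here.

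The peak at the start of E(bx) was the strongest in the pooled list, at 2.26 times the next. A single aberrant library is argued against, since the ratio to the next peak was 2.12, 2.29 and 2.07 in the 3 libraries. Extra copies of the locus from the transgene could raise signal over all of the gene, yet relaxed peaks covered 0% of the E(bx) body away from its start, at percentile 10.8 of 588 occupied genes of 10 to 20 kb (median 8.34%). The bound written down first would have counted this against extra copies, but that verdict was withdrawn after the value was seen, because weak relaxed peaks were denser on X than on autosomes (ratio 1.40, 95% interval 1.35 to 1.45) and so are not shown to follow copy number. Extra copies stay open, as it is not known whether the control carried them too, and no biological explanation was tested, as the design has 1 group.

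Peaks on X were more frequent per start site but weaker than those on autosomes. A larger share of distal peaks is argued against as the whole cause, since among promoter peaks alone the median signal on X was 0.793 times that on autosomes (95% bootstrap interval 0.748 to 0.847). A lower X copy number in embryos of both sexes predicts about 0.75 at genes occupied on every chromosome. This needs a signal value that is proportional to copy number and not corrected for it by the control. Neither is given in the sources used here, so a ratio near 0.75 cannot decide the question. At the genes of the 4 housekeeping lists the ratio was 0.711 (0.532 to 0.856, 35 genes on X against 184 on autosomes), and 0.756, 0.693 and 0.708 in the lists of replicates 1, 2 and 3. Copy number stays a candidate explanation for the weaker signal, other reasons for weaker binding on X were not tested, and the higher number of X peaks is not accounted for by it.

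Transfer RNA genes often had a peak within 500 bp. Peaks of neighbouring promoters of other kinds of genes are argued against as the whole cause. Of 193 transfer RNA genes with no start site of another kind of gene within 1000 bp, 120 (62.2%) had a peak. Of 8842 other genes with no start site of any other gene within 1000 bp, 2366 (26.8%) had one. The odds ratio was 4.5 (95% interval 3.1 to 6.52 from resampling the 119 groups of neighbouring transfer RNA genes). The groups are not alike, as only the transfer RNA genes could have neighbours of their own kind. Clustering is not argued against: of the 70 transfer RNA genes with no other start site of any kind within 1000 bp, 26 (37.1%) had a peak, against the same 26.8% (odds ratio 1.62, 0.954 to 2.69). Peaks shared within clusters therefore stay open as a source of the high share. Of the 131 peaks involved, 29.8% were in the stronger part of the set, and highly transcribed loci that precipitate with any antibody stay open, as control data were not analysed here.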

How the results depend on the processing

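The libraries' own lists set against each other, all pooled peaks outside the set as comparison for the promoter share, start site windows as motif comparison, the single summit per region, the transposable elements counted as genes and both rescalings of X signal were chosen after seeing the data. Of the comparisons of a main result with an alternative, 105 kept their call and 3 did not: direction and side of the threshold for tests, within 1.5 times for counts, within 1 SD for the rank correlation. The promoter share ranged from 66.8% (250 bp window) to 80.9% (1000 bp window) with the window, the share found in all libraries from 41.8 to 97.1%, the number of gene lists past the threshold from 17 to 19 and that of motifs more frequent at summits from 9 to 12. The total of lists hides a shift from 10 higher and 9 lower to 6 and 11 among the strongest peaks. The 3 exceptions came from keeping the strongest peaks: a peak count of 4854 by construction, a mean rank correlation of 0.756 instead of 0.852, and an X density ratio of 0.896 instead of 1.17. Rescaling X signal upward gave 1.17 or 1.22, but must raise this ratio whatever the cause and so explains nothing. The same selection turned transfer RNA genes to -10.9 points, dorsoventral and mesoderm genes to -27.3 and the CA repeat to -0.412. Windows of 50 bp turned the TATA box (-0.505) and the Twist E-box (0.0618). The dinucleotide shuffle turned the CACGTG E-box (-0.577), the initiator (1.16), the GATA site (0.165) and the Twist E-box (0.0206). Start sites without a peak turned the TATA box (-2.34) and the Twist E-box (0.267), and with both windows on start sites the TATA box (-6.14) and the Su(Hw) core (-0.0291). The cause was not tested for any of these. Over single lists and motifs 439 comparisons were unchanged, 28 lost significance, 3 gained it in the same direction, 13 turned as listed, and 32 not past the threshold changed sign or went to 0. No paired analysis was possible because there is 1 group.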

Other observations

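The signal of promoter peaks by motif and the density of weak peaks on X were tests chosen only after related results were seen.

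Promoter peaks differed in strength with the elements they carried. Those with Motif 1 had a median signal of 927 against 571 without it (ratio 1.62, 833 and 6363 peaks), and the ratio was 1.37 for Motif 7, 1.36 for Motif 6 and 1.29 for the CTCF core. Promoter peaks with the GAGA repeat were weaker (322 against 639, ratio 0.503, 486 and 6710 peaks), as were those with CA repeats (335 against 627, ratio 0.534) and the GATA site (ratio 0.855). In all, 5 of the 17 elements went with higher and 4 with lower signal (permutation test with 10000 resamples, Benjamini-Hochberg over the 17; adjusted p = 0.000243 for the GAGA repeat, Motif 1 and CA repeats, which is the smallest raw p of 0.0001 after adjustment).

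The ratio was 1.19 for the DRE (712 against 598, permutation test, adjusted p = 0.000243) and 0.806 for the initiator (512 against 636, permutation test, adjusted p = 0.000243). The directions for all elements with higher or lower signal were visible in results already at hand. The DRE was at 14.4% of the promoter summits among the 4854 strongest peaks against 12.2% of all promoter summits, and the initiator at 15.3% against 17.8%. By the same comparison Motif 1 was at 16.9% against 11.6% and the GAGA repeat at 3.16% against 6.75%. Motif 6, Motif 7 and the CTCF core likewise rose, and CA repeats and the GATA site fell. The ratios of all these elements restate those differences and test no prediction. Windows were centred on the summit, so they miss some start sites. Peaks are not independent replicates, and expression of the genes was not analysed here.

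Weak peaks of the pooled list, over 1000 bp from any reproducible summit, were denser on X, with 161 per Mb (3787 peaks) against 115 per Mb on the large autosomal arms (12542 peaks). The ratio of 1.40 is above that of 1.06 per sequence length for the reproducible peaks.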
